A study of Homo sapiens with 8 samples.

How the data were processed

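RNA from 8 samples of MDA-MB-231 cells, 4 wild-type and 4 DOT1L knockout (DOT1L/+), was sequenced on a NextSeq 2000 as stranded libraries of total RNA depleted of ribosomal RNA, per the labels' protocols. The deposited table of counts holds whole-number counts per Ensembl gene for each sample, and the submitters' processing notes name STAR 2.6.0c, featureCounts, Subread 1.6.2, FastQC 0.11.7, DESeq2 1.23.10 and the build hg38 without parameters. The authors also deposited log2-scale values from a variance-stabilizing transformation, in which every count of 0 has the same floor value of 5.59. The annotation release, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Counts of EEF1A1P5, a processed pseudogene, came to 99.7% of those of EEF1A1, so reads shared by near-identical copies appear to have been counted at each copy, and levels of histone, ribosomal protein and other multicopy genes are uncertain.

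Groups and replicate numbers came from the sample labels, and columns of both tables were matched to samples by name. The labels do not say whether the samples of a group came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical. No pair of replicates of a group was alike within sampling noise, with chi-square per degree of freedom from 3.41 to 18.4 over genes with at least 20 counts. Both groups carry replicate numbers 1, 2, 3 and 5. Deviations from the group means correlated between same-numbered samples at 0.369, 0.148, 0.146 and 0.373 over 13344 genes, against -0.302 to 0.0587 for other pairs, and 8 of 8 samples correlated best with their own number. Every pair lay above the minimum of 0.1, so the numbers were taken to pair the samples, a pairing that comes from these correlations and shared labels.

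Of 60646 genes in the count table, 60333 identifiers matched a table of gene symbols and 58459 matched GENCODE 29 on GRCh38 (the same build as hg38), which gave coordinates, gene types, lengths and sequences. Of the genes of the mitochondrial genome 0 were matched in the table, and they were not analysed here. Totals per sample ran from 40103408 to 50031412 counts, so that 1 count stood for 0.0198 to 0.0250 CPM. Counting intervals (95%) and floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules.

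The comparison of knockout with wild-type was made on the deposited counts in R 4.3.3 with edgeR 4.0.16, using filterByExpr, trimmed-mean (TMM) scaling, robust quasi-likelihood fits and Benjamini-Hochberg adjusted p below 0.05, with group as the single term. CPM were computed with TMM factors, and log2 CPM for correlations and components used a prior count of 2, the components being taken over the 500 most variable genes. Gene lists fixed before the data were examined (35 lists, 31 with at least 5 tested members) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. Each adjusted p quoted for a gene comes from edgeR's quasi-likelihood test, and each quoted for a list from camera unless another test is named.

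Named genes followed a rule fixed before the data were examined. It took DOT1L, TXNIP, ARRDC4 and the tested members of the MYC, MAX and MLX network. It added the 10 largest rises and 10 largest falls among protein-coding genes with adjusted p below 0.05, mean log2 CPM of at least 1 and groups that did not overlap, and the 2 largest of each direction among non-coding genes. It took the 3 members with the smallest adjusted p from each called list and up to 2 passing members from each other list. Genes that tell sex were never named. A few genes that the rule or the lists hold are not reported here by name. Names outside the rule are said to have been chosen after their values were seen.

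The procedure was tested on simulated data drawn from the wild-type means, the library sizes and the fitted dispersions of these samples. Of 19877 genes 200 were changed, in random directions, far fewer than the 9458 called in the real data. The procedure was therefore not tested on so broad a change. For this comparison it recovered 85.1% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 7.77% of 206 calls were false. The changed genes were drawn from those with a mean log2 CPM above 0, so recovery among lower genes was not measured. In a separate draw a list moved by 0.3 was called and 0 of 20 random lists of 30 genes were. The genes of these lists had a mean log2 CPM above 2. Genes varied independently in that draw, whereas the estimated correlation reached 0.79 for the histone list of these samples. The draw therefore does not give the rate of false calls for correlated lists. With a simulated lower dose of a stretch of 496 genes, the neighbour median was -0.80 inside it and 0.01 on other autosomes, and 365 genes were called before centring and 0 after.

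The alternatives fixed before the data were examined were RLE, upper-quartile and no composition scaling, DESeq2 1.42.0, limma-voom, limma on the authors' variance-stabilized values, 3 other filters, protein-coding genes alone, the replicate number as a block, each sample left out in turn, the other set tests, and lists without members that another list holds. After the data were seen, regional centring was added, in which the median change of the 25 expressed protein-coding neighbours on each side (log2 CPM of at least 2) was taken out of the knockout samples as an offset, together with a fit without genes whose neighbour median lay beyond 0.2. Genes that filterByExpr set aside for low counts were left out of the tests, and a fit of all genes with at least 1 count was among the alternatives.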

Results

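Transcript levels were measured by RNA-seq in MDA-MB-231 cells, an established human line from a triple-negative breast cancer. The 8 samples formed 2 groups, 4 wild-type and 4 labelled as a DOT1L knockout (DOT1L/+), made with a guide against the first exon. The labels do not say how many alleles were edited or what the edit was, and knockout here stands for that label. The libraries held total RNA depleted of ribosomal RNA. The counts assigned to genes totalled 43183067, 40103408, 50031412 and 46337448 for wild-type replicates 1, 2, 3 and 5, and 47734419, 46713622, 47000464 and 49308625 for knockout replicates 1, 2, 3 and 5. The series title places the comparison in the study of how DOT1L, the methyltransferase that modifies H3K79, acts on the turnover of the transcription factors MYC and Mondo on chromatin. The comparison made here asks which transcripts differed in level between the groups.

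DOT1L itself (ENSG00000104885, chromosome 19, 2164149 to 2232578, plus strand) was measured first, since it is the targeted gene. Its level in wild-type replicates 1, 2, 3 and 5 was 114.67, 100.88, 103.26 and 118.35 CPM (counts scaled to a common library total). In the knockout replicates 1, 2, 3 and 5 it was 85.256, 78.069, 83.207 and 92.327 CPM. The group means were 109 ± 8.52 CPM and 84.7 ± 5.91 CPM (SD, n = 4 each), with all 4 knockout samples below all 4 wild-type samples. The log2 change was -0.37 (SE 0.06, adjusted p = 2.83e-05). The median change of its chromosomal neighbours was -0.17, and relative to them DOT1L fell by 0.20 on the log2 scale (adjusted p = 0.00886). A gene-level count includes reads from an edited allele, so it does not measure how much intact transcript remained.

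Of 19877 genes tested, 9458 changed, 4759 of them higher and 4699 lower in the knockout. At a change of at least 2-fold, 1336 were higher and 525 lower. Most calls were small, with 5105 of the changed genes (54.0%) under 0.5 on the log2 scale. All values of one group lay above all values of the other for 43.4% of the tested genes, where chance gives 2.86%. The balance of directions depended on the scaling. Higher calls made up 50.3% of changed genes with trimmed-mean scaling, 61.2% (5905 higher, 3744 lower) with library totals alone and 61.9% (6021 higher, 3705 lower) with upper-quartile scaling. Samples of one group correlated at 0.993 to 0.996 over log2 CPM and samples of different groups at 0.968 to 0.970, and the first principal component, which held 95.2% of the variance, parted the groups.

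Among protein-coding genes with a mean log2 CPM of at least 1 and groups that did not overlap, those with the largest rises went from near absence to clear expression. VWA5A rose from 0.0290 ± 0.0216 to 22.1 ± 1.55 CPM (n = 4 each, adjusted p = 4.68e-19). ANO5, a membrane protein of the anoctamin family, had 2 counts over the wild-type group and 876 over the knockout group, a ratio of 395 after scaling to library size (95% counting interval 109 to 3264). EPHA3, an ephrin receptor, rose from 0.177 ± 0.0469 to 7.83 ± 0.490 CPM. SLITRK2 rose from 0.338 ± 0.10015 to 13.97 ± 0.837 CPM and NAALAD2 from 0.349 ± 0.169 to 14.4 ± 0.715 CPM. RSAD2, an interferon-induced antiviral protein, rose from 0.226 ± 0.0875 to 5.70 ± 0.979 CPM. FPR2, OPN4, PCDH17 and ELMO1 rose with log2 changes of 4.89, 4.87, 4.62 and 4.54. Among non-coding genes within the same limits the largest rises were those of ENSG00000260073 (5.84) and LINC02188 (5.18).

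Among protein-coding genes with a mean log2 CPM of at least 1 and groups that did not overlap, the largest falls ended near 0 counts. PNMA8A had 3333 counts over the wild-type group and 0 in every knockout library, at least 309-fold lower against a floor of 3 counts per library. CCDC8 kept 3 counts over the knockout group against 2383 in wild-type, a ratio of 881 (95% counting interval 301 to 4277). For ZNF43, a zinc finger gene, the counts were 1896 and 3 (ratio 701, interval 240 to 3404). ASRGL1 had 1562 and 3 counts (ratio 578, interval 197 to 2805), and TBX3, a T-box transcription factor, had 899 and 2 (ratio 499, interval 138 to 4125). IRAK3, a negative regulator of Toll-like receptor signalling, fell from 8.38 ± 0.903 to 0.0206 ± 0.0296 CPM (n = 4 each). CPE, a carboxypeptidase that processes peptide hormones, fell from 4.82 ± 1.11 to 0.0208 ± 0.0171 CPM. The zinc finger genes ZNF90, ZNF100 and ZNF736 fell with log2 changes of -7.21, -7.00 and -6.78. The non-coding gene AFAP1-AS1 fell from 122.9 ± 10.1 to 0.0408 ± 0.0286 CPM, while the gene it overlaps on the opposite strand, AFAP1, named after its value was seen, changed by -0.17 (adjusted p = 0.00488) and stood at -0.04 relative to its neighbours (adjusted p = 0.582). The strand setting of the counting was not given in the sources used here, so reads of such a pair could have been shared. The pseudogene AADACP1 fell from 12.9 ± 2.27 to 0.643 ± 0.132 CPM.

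Within the network of factors that pair with MAX or MLX, MYC itself fell and no member rose. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand), a transcription factor of growth and ribosome production, fell from 192.5 ± 14.2 to 124 ± 5.68 CPM (SD, n = 4 each), a log2 change of -0.63 (SE 0.05, adjusted p = 3.12e-09). MAX, its obligate partner, fell from 116 ± 6.01 to 103 ± 1.78 CPM (log2 change -0.18, adjusted p = 0.00322). MGA fell by 0.21, or by 0.35 relative to its chromosomal neighbours, and MXD1, a MAX-binding repressor, by 0.24 on the log2 scale. MLX, the partner of the Mondo proteins, fell from 97.3 ± 3.02 to 89.6 ± 2.53 CPM (log2 change -0.12, adjusted p = 0.0310). MLXIP, which encodes the Mondo protein MondoA, stood at 139 ± 1.95 and 139 ± 5.73 CPM (log2 change -0.01, adjusted p = 0.937). MNT (-0.07), MXD4 (-0.11), MXI1 (0.09), MXD3 (0.20), MYCL (0.41) and MLXIPL (0.17) did not pass. In all, 0 of 12 tested members rose, 5 fell and 7 did not pass, with the same 5 when adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.397).

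The MLX call was lost with upper-quartile scaling (adjusted p = 0.305), with library totals (0.248), with only genes of mean log2 CPM of at least 1 (0.0614) and without wild-type replicate 1 (0.0549) or 3 (0.0653) or knockout replicate 2 (0.0813) or 5 (0.0914). MXD3 passed with the replicate number as a block (adjusted p = 0.00487), with upper-quartile scaling (0.0456), with the lenient filter (0.0265) and without wild-type replicate 1 (0.0162) or knockout replicate 3 (0.0329), and MXD4 passed without wild-type replicate 3 (0.0116).

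Among the targets of the Mondo proteins, TXNIP and ARRDC4, arrestin-domain proteins that restrain glucose uptake, both rose. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600, minus strand) rose from 52.7 ± 4.83 to 71.3 ± 5.11 CPM (n = 4 each), a log2 change of 0.44 (SE 0.06, adjusted p = 1.18e-05). ARRDC4 rose from 6.25 ± 0.387 to 8.12 ± 0.690 CPM (log2 change 0.38, adjusted p = 0.00178). THBS1 rose from 455 ± 99.2 to 1025 ± 55.8 CPM and GPD1, a gene at the edge of detection, from 0.116 ± 0.0546 to 0.303 ± 0.0724 CPM. HK2, which carries out the entry step of glycolysis, fell from 232 ± 13.7 to 146 ± 8.21 CPM. THBS1 and GPD1 were named after their values were seen. Of 14 tested targets, 4 rose, 1 fell and 9 did not pass, the same when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.506). With upper-quartile scaling 6 rose and 1 fell. With the replicate number as a block, 12 genes of the MYC network and these targets together passed, against 10 without it. Of the arrestin-domain family, 2 of 5 tested members, TXNIP and ARRDC4, rose and 3 did not pass (same counts adjusted over the list alone, camera adjusted p = 0.384).

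**Figure D1:**
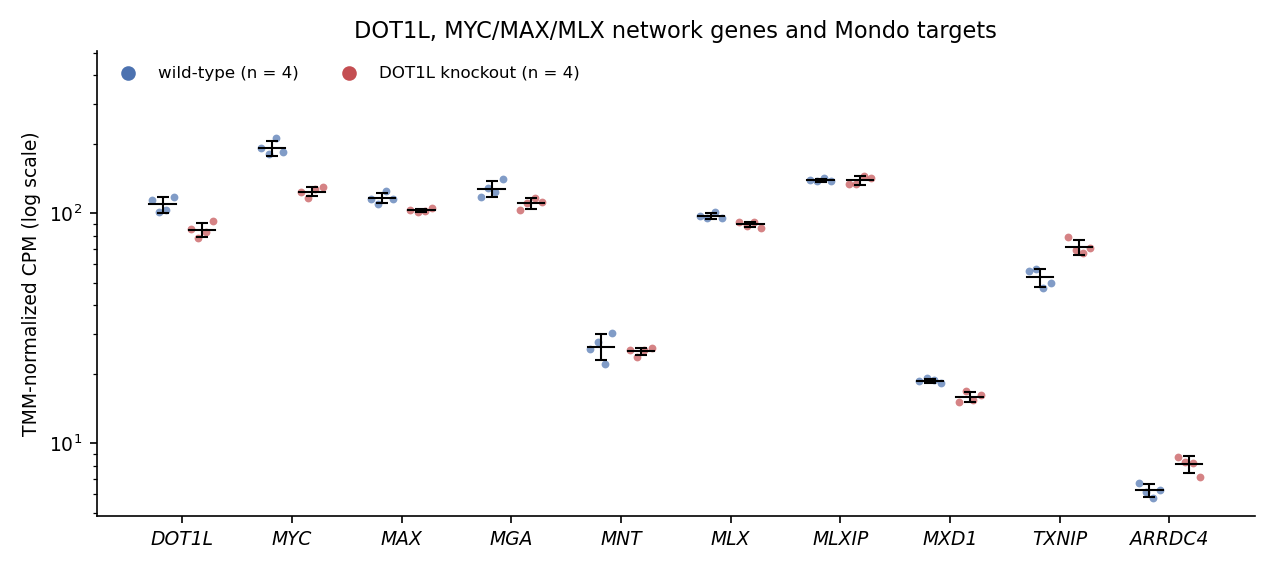
Levels of DOT1L, MYC network members and Mondo targets in each of the 8 samples, in CPM after trimmed-mean scaling on a log axis, with points for samples and bars for the mean ± SD of each group (n = 4). MYC stood at 192.5 CPM in wild-type and 124 CPM in knockout samples, and TXNIP at 52.7 and 71.3 CPM.

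The growth-related lists moved down. Replication-dependent histone genes, which supply histones for new chromatin, had 0 of 33 tested members higher, 32 lower and 1 not passed, with 32 passing adjusted over the list alone (camera adjusted p = 1.07e-08, adjusted p = 0.638 with an estimated correlation). Relative to neighbours 1 of them rose and 22 fell, but the neighbours of a clustered histone gene include other histone genes, so part of the list's own fall was taken out. H2AC4 fell from 127 ± 7.96 to 71.5 ± 2.85 CPM, H4C2 from 344 ± 22.3 to 214 ± 14.7 CPM and H2AC21 from 33.7 ± 2.79 to 18.8 ± 0.899 CPM (n = 4 each). Of 78 cytosolic ribosomal protein genes, 3 rose (RPL28 and RPLP1 among them, named after their values were seen), 50 fell and 25 did not pass, with 54 passing adjusted over the list alone (camera adjusted p = 2.44e-05, adjusted p = 0.789 with an estimated correlation). With library totals 7 rose and 37 fell, with upper-quartile scaling 7 and 33, and relative to neighbours 2 and 38. RPS16 fell from 431 ± 34.1 to 208 ± 8.89 CPM, RPL29 from 336 ± 16.2 to 192 ± 5.74 CPM and RPS3A from 60.4 ± 3.91 to 27.8 ± 2.39 CPM. Relative to their neighbours the log2 changes of RPL29 and RPS3A were -0.33 and -0.27, against -0.80 and -1.12 without that adjustment. Nucleolar and ribosome-biogenesis targets of MYC had 2 members higher (NOP2 and NPM1, named after their values were seen), 24 lower and 27 not passed of 53, with 26 passing adjusted over the list alone (camera adjusted p = 0.0245, adjusted p = 0.789 with an estimated correlation). The nucleoside transporter SLC29A2 (-1.33), PRMT3 (-0.78) and the nucleolar GTPase GNL3 (-0.57) led the list. All of these lie in neighbourhoods that were lower as a whole, and relative to their neighbours SLC29A2 and PRMT3 stood at -0.82 and -0.36 and GNL3 at -0.04 (adjusted p = 0.535). With library totals 6 of the 53 genes rose and 17 fell, and with upper-quartile scaling 5 and 16. Relative to neighbours 0 rose and 17 fell, and NOP2 and NPM1 stood at -0.08 and 0.00 (adjusted p = 0.615 and 0.988). The call of the MYC targets was lost without wild-type replicate 3 (adjusted p = 0.107) and among genes of mean log2 CPM of at least 1 (0.133). Histone and ribosomal protein genes have near-identical copies and pseudogenes, so their levels are uncertain where reads could be shared.

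Lipid synthesis genes fell. Of 15 genes of fatty acid synthesis, 2 rose (ACACB and GPAM, named after their values were seen), 10 fell and 3 did not pass, with 12 passing adjusted over the list alone (camera adjusted p = 2.44e-05, adjusted p = 0.0967 with an estimated correlation). ELOVL6, a fatty acid elongase, fell from 97.7 ± 2.02 to 35.9 ± 4.17 CPM, ME1, which supplies NADPH, from 39.9 ± 4.43 to 16.6 ± 0.466 CPM, and the desaturase FADS2 from 330.01 ± 27.5 to 178 ± 8.21 CPM (n = 4 each). Relative to their neighbours the log2 changes of ELOVL6 and FADS2 were -0.59 and -0.46. Of 24 genes of cholesterol synthesis, 2 rose (SC5D and PMVK, named after their values were seen), 18 fell and 4 did not pass, with 20 passing adjusted over the list alone (camera adjusted p = 9.73e-05, adjusted p = 0.638 with an estimated correlation). With library totals 14 of them fell and with upper-quartile scaling 15. DHCR7, an enzyme of the last part of the pathway, fell from 84.7 ± 3.79 to 40.9 ± 3.43 CPM, and SREBF2, the transcription factor that drives the pathway, from 161 ± 4.83 to 95.045 ± 8.91 CPM (n = 4 each). Relative to its neighbours DHCR7 fell by 0.60, against 1.05 without that adjustment.

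Stress-response lists also moved down. Of 18 genes of the unfolded protein response, 1 rose (CANX, named after its value was seen), 11 fell and 6 did not pass, with 13 passing adjusted over the list alone (camera adjusted p = 0.00186, adjusted p = 0.638 with an estimated correlation). PDIA4, a protein disulphide isomerase, fell from 284 ± 14.99 to 163 ± 2.98 CPM, MANF from 86.6 ± 2.82 to 52.3 ± 1.52 CPM and HERPUD1 from 50.4 ± 1.92 to 36.2 ± 0.644 CPM (n = 4 each). Relative to their neighbours the log2 changes of MANF and HERPUD1 were -0.27 and -0.21, against -0.73 and -0.48 without that adjustment. Of 24 genes of the integrated stress response, 1 rose, 19 fell and 4 did not pass, with 22 passing adjusted over the list alone (camera adjusted p = 0.00472, adjusted p = 0.638 with an estimated correlation). ATF4, its central transcription factor, fell from 274 ± 12.2 to 221 ± 9.70 CPM and SESN2 from 10.8 ± 1.86 to 6.58 ± 0.448 CPM, while STC2 rose from 1.504 ± 0.0471 to 2.96 ± 0.141 CPM.

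Other lists moved up. Of 41 interferon-stimulated genes, 22 rose, 12 fell and 7 did not pass, with 34 passing adjusted over the list alone (camera adjusted p = 0.00186, adjusted p = 0.638 with an estimated correlation). IFIT1, which binds foreign RNA, rose from 11.8 ± 1.13 to 70.9 ± 4.44 CPM, ISG15, a ubiquitin-like modifier, from 18.2 ± 1.47 to 65.3 ± 2.37 CPM and IFI44 from 18.04 ± 1.88 to 49.8 ± 2.47 CPM (n = 4 each). Members that went the other way, named after their values were seen, were the antiviral membrane proteins BST2 (-4.22) and IFITM1 (-2.61) and the transcription factor IRF7 (-0.91). Of 24 TGF-beta targets, 14 rose, 5 fell (TGFB1, BMPR2, TGIF1, SMURF1 and LTBP3, named after their values were seen) and 5 did not pass, with 20 passing adjusted over the list alone (camera adjusted p = 0.000423, adjusted p = 0.638 with an estimated correlation). With library totals or upper-quartile scaling 17 rose and 3 fell. ID2 rose from 3.40 ± 0.409 to 17.7 ± 2.96 CPM, PMEPA1 from 7.80 ± 0.744 to 21.97 ± 1.47 CPM and BAMBI from 3.86 ± 0.431 to 6.9989 ± 0.550 CPM. ID2 is an inhibitor of differentiation factors, and PMEPA1 and BAMBI are feedback inhibitors of TGF-beta signalling.

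Of 24 mesenchymal genes, 9 rose, 6 fell and 9 did not pass, with 16 passing adjusted over the list alone (camera adjusted p = 0.0327, adjusted p = 0.638 with an estimated correlation). The matrix protease MMP3 rose from 8.74 ± 0.667 to 47.9 ± 4.53 CPM and the transcription factor SNAI1 from 4.44 ± 0.336 to 11.3 ± 0.738 CPM, while the calcium-binding protein S100A4 fell from 4.44 ± 0.586 to 1.95 ± 0.262 CPM (n = 4 each). The list's median change was 0.06 and its mean 0.41. Its call was lost without wild-type replicate 2 (adjusted p = 0.0571) or 5 (0.0534) and without members that another list holds (0.0625). Of 21 p53 targets, 12 rose, 4 fell (CCNG1, TNFRSF10B, PHLDA3 and BBC3, named after their values were seen) and 5 did not pass, with 16 passing adjusted over the list alone (camera adjusted p = 0.0475, adjusted p = 0.638 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 43.9 ± 3.48 to 89.3 ± 1.26 CPM, TIGAR from 9.79 ± 0.173 to 19.3 ± 0.914 CPM and ZMAT3 from 38.8 ± 3.12 to 61.9 ± 4.51 CPM. The log2 change of TIGAR was 0.98, or 0.61 relative to its neighbours. The p53 call was lost without wild-type replicate 5 (adjusted p = 0.0734), without knockout replicate 1 (0.0531), 2 (0.0660) or 3 (0.0504), and without members that another list holds (0.0545). It was also lost relative to chromosomal neighbours (adjusted p = 0.0807) and without genes in shifted neighbourhoods (0.277).

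Of the 31 lists with at least 5 tested members, 11 were called, 4 up and 7 down, and 0 by camera with an estimated correlation, where 1 list, fatty acid synthesis, had an unadjusted p below 0.05 (p = 0.00312). The rotation test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 23. Other splits of the 8 samples into 4 and 4 called as many as 16 lists, so chance is not excluded for the number of lists.

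**Figure D2:**
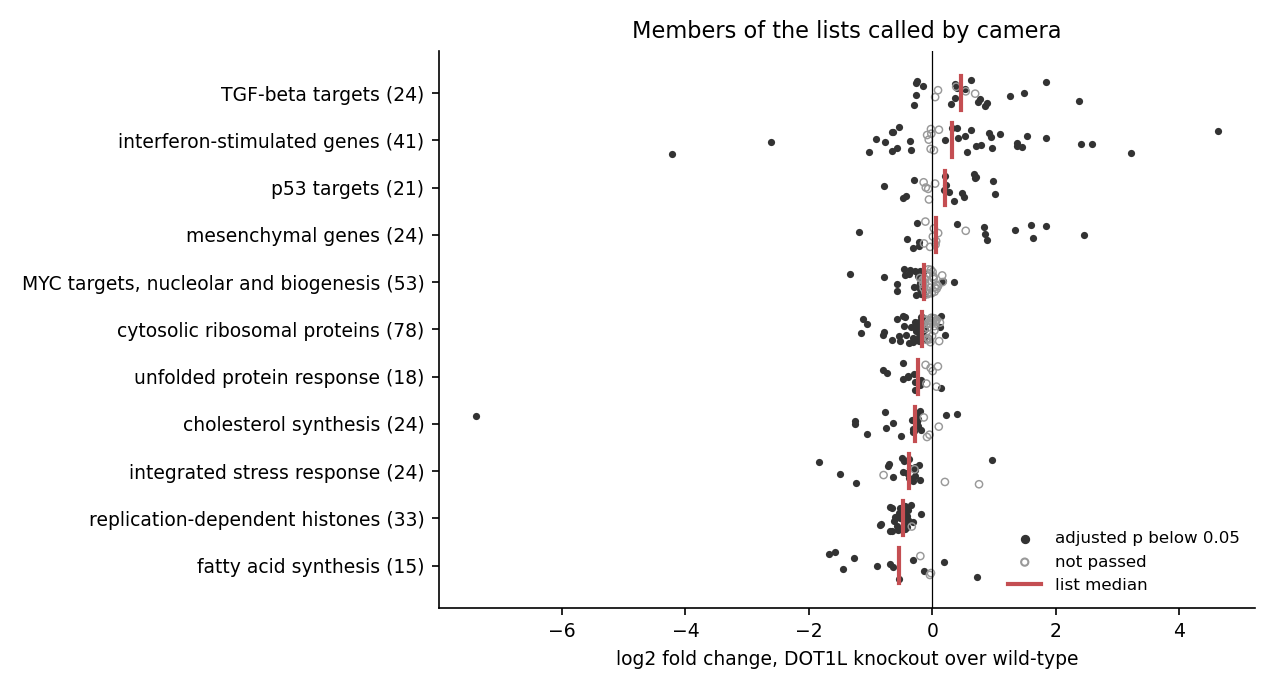
Log2 change of the members of the 11 called lists, knockout against wild-type, with a point for each tested gene, filled where the adjusted p was below 0.05, and a red line at each list's median. All 33 histone genes lay below 0, and the interferon-stimulated genes ran from -4.22 to 4.63.

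The remaining lists did not pass as sets, although single members changed. Of 31 regulators of H3K79 and other chromatin marks, 4 rose (KMT2A, KDM5A, NSD3 and SETD1B, named after their values were seen), 17 fell and 10 did not pass (camera adjusted p = 0.0544), and 6 rose and 12 fell with library totals or upper-quartile scaling. The set passed, as lower, with the lenient filter (adjusted p = 0.00223), without members that another list holds (0.0269), and without wild-type replicate 1 (0.0434), 2 (0.0362) or 3 (0.0491) or knockout replicate 5 (0.0316). Among its members the acetyltransferase KAT5 fell by 0.83 on the log2 scale, or by 0.40 relative to its neighbours, and KDM2A stood at -0.56, or -0.07 relative to its neighbours (adjusted p = 0.220). Of 20 members of the DOT1L-containing complexes, 7 rose, 5 fell and 8 did not pass (0.852). MLLT3, a reader that recruits DOT1L, fell from 30.2 ± 1.24 to 17.9 ± 0.686 CPM, and AFF3, a scaffold of the elongation complex, rose from 9.13 ± 1.05 to 18.4 ± 1.56 CPM (n = 4 each). Of 15 genes of MHC class I and antigen presentation, 1 rose (HLA-F, named after its value was seen), 7 fell and 7 did not pass (camera adjusted p = 0.107), and the set passed, as lower, relative to chromosomal neighbours (0.00741) and with the lenient filter (0.00835). With library totals or upper-quartile scaling 4 of these genes rose and 6 fell. In that list the peptidase ERAP1 fell by 0.96 and the transactivator NLRC5 by 0.78 on the log2 scale, or by 0.51 relative to its neighbours. Adjusted over the list alone, the counts of these lists were the same.

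Cell cycle and metabolic lists held members of both directions. Of 40 genes of G2/M and mitosis, 18 rose, 6 fell and 16 did not pass (camera adjusted p = 0.293), with 25 passing adjusted over the list alone. With library totals or upper-quartile scaling 24 rose and 3 fell. CCNA2, a cyclin, fell by 1.05 on the log2 scale, or by 0.17 relative to its neighbours (adjusted p = 0.0203). FOXM1, a mitotic transcription factor, stood at 0.38 in the fit without neighbours and at -0.02 relative to them (adjusted p = 0.701). Of 43 E2F targets and replication genes, 6 rose, 14 fell and 23 did not pass (camera adjusted p = 0.293), with 21 passing adjusted over the list alone. The balance turned with library totals (13 rose, 12 fell), with upper-quartile scaling (15 and 11) and relative to neighbours (12 and 8). E2F8 and GINS2 fell by 0.80 and 0.62, or by 0.39 and 0.35 relative to their neighbours. The set passed, as lower, with the lenient filter (adjusted p = 0.0464). Of 24 glycolysis genes, 9 rose, 8 fell and 7 did not pass (camera adjusted p = 0.954), with 18 passing adjusted over the list alone. The counts became 9 and 5 with library totals, 9 and 4 with upper-quartile scaling, and 4 and 4 relative to neighbours. GAPDH stood at 0.43, or 0.04 relative to its neighbours (adjusted p = 0.589). Of 54 nuclear-encoded respiratory chain genes, 12 rose, 12 fell and 30 did not pass (camera adjusted p = 0.852), with 24 passing adjusted over the list alone. The counts became 20 and 10 with library totals or upper-quartile scaling, and 21 and 5 relative to neighbours. UQCRC1 fell by 0.77, or by 0.19 relative to its neighbours, and NDUFV1 stood at -0.47, or -0.00 relative to its neighbours (adjusted p = 0.961). Of 22 hypoxia genes, 5 rose, 13 fell and 4 did not pass (camera adjusted p = 0.180), with 18 passing adjusted over the list alone, and ERO1A fell by 0.48. With library totals or upper-quartile scaling 5 of the hypoxia genes rose and 9 fell. The hypoxia set passed, as lower, with the lenient filter (adjusted p = 0.0295) and without wild-type replicate 3 (0.00677). Of 24 NRF2 targets, 5 rose, 12 fell and 7 did not pass (camera adjusted p = 0.137), with 18 passing adjusted over the list alone. The NRF2 set passed, as lower, with the lenient filter (adjusted p = 0.0186) and without wild-type replicate 2 (0.0438) or 3 (0.0473). The aldo-keto reductase AKR1C2 rose from 0.331 ± 0.0339 to 2.36 ± 0.368 CPM (n = 4 each).

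Signalling and lineage lists were mixed as well. Of 27 NF-kB and inflammatory genes, 12 rose, 8 fell and 7 did not pass (camera adjusted p = 0.925), with 21 passing adjusted over the list alone. CSF1 fell from 74.3 ± 8.19 to 32.1 ± 2.15 CPM and NFKB1 by 1.14 on the log2 scale, or by 0.29 relative to its neighbours. Of 32 immediate early genes, 13 rose, 6 fell and 13 did not pass (camera adjusted p = 0.384), with 20 passing adjusted over the list alone. FOS rose by 0.84 and SPRY4 by 0.41. The counts became 17 and 5 with library totals and 16 and 5 with upper-quartile scaling. Of 26 YAP/TEAD targets, 8 rose, 10 fell and 8 did not pass (camera adjusted p = 0.428, 18 passing adjusted over the list alone), and TGFB2 and RBMS3 fell by 0.97 and 0.74. The YAP/TEAD balance turned with library totals (9 rose, 8 fell) and with upper-quartile scaling (10 and 8). Of 16 epithelial genes, 6 rose, 7 fell and 3 did not pass (camera adjusted p = 0.993, 13 passing adjusted over the list alone), and SPINT2 fell by 0.89. Relative to neighbours 7 epithelial genes rose and 4 fell. Of 14 luminal breast markers, 7 rose, 4 fell and 3 did not pass (camera adjusted p = 0.551, 12 passing adjusted over the list alone). In that list the keratin KRT8 rose from 310 ± 26.4 to 540.4 ± 62.7 CPM and XBP1 fell by 0.48. Of 30 collagen and matrix genes, 15 rose, 11 fell and 4 did not pass (camera adjusted p = 0.137, 26 passing adjusted over the list alone), and COL5A2 and FBLN5 rose by 1.54 and 1.14. The matrix set passed, as higher, without wild-type replicate 3 (adjusted p = 0.0473).

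Some markers of other cell types rose. Of 7 tested fibroblast markers, 4 rose (COL3A1, COL1A1, ACTA2 and FBLN1) and 1 fell (PDPN), and 2 did not pass (camera adjusted p = 0.107, 5 passing adjusted over the list alone). With library totals, with upper-quartile scaling and relative to neighbours 4 rose and 0 fell. COL1A1 rose from 10.2 ± 2.11 to 18.7 ± 1.06 CPM and COL3A1 from 0.203 ± 0.108 to 2.06 ± 0.613 CPM (n = 4 each), beside the 9 mesenchymal and 15 collagen and matrix genes that rose. Of 5 tested leukocyte markers, 3 rose (CSF1R, CD8A and CD68) and 2 did not pass (camera adjusted p = 0.384, 4 passing adjusted over the list alone), beside the 22 interferon-stimulated genes that rose. Relative to neighbours 2 leukocyte markers rose and 0 fell. CSF1R rose from 0.686 ± 0.243 to 1.43 ± 0.354 CPM and CD8A from 1.63 ± 0.387 to 2.45 ± 0.312 CPM. Lists with fewer than 5 tested members had no set test. The HOXA and MEIS1 list had 3 tested members, of which PBX3 fell (-0.14, not passed with library totals or upper-quartile scaling) and 2 did not pass. Markers of HEK-like lines had 3 tested members, of which 2 rose, EYA1 (2.10) and CRABP2 (0.96), and 1 fell. RN7SL1, the single tested abundant small RNA and the gene with the most counts, fell by 0.17, and not with library totals or upper-quartile scaling. Of the mitochondrially encoded mRNAs 0 were tested. Counts of the lists with fewer than 5 tested members were the same adjusted over the list alone. Markers of all these kinds beyond COL3A1, COL1A1, CSF1R and CD8A were named after their values were seen. The median, mean and test differed in sign for the respiratory chain, glycolysis, epithelial and DOT1L complex lists.

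Changes also followed chromosome position, a pattern looked for after the values were seen. On chromosome 4 the median change of 391 expressed protein-coding genes was -0.73, the lowest of 23 chromosomes, followed by chromosome 11 (-0.33), 16 (-0.14) and 3 (-0.11), with chromosome 15 at the other end (0.12). Beyond 50 Mb of chromosome 4, 248 of 267 genes fell and 10 rose, with a median of -0.84, a ratio of 0.557, while the 124 genes before 50 Mb had a median of -0.07. Other stretches were lower as well, such as 40 to 50 Mb of chromosome 3 (median -0.58, 84 of 97 genes lower), the first 10 Mb of chromosome 5 (-0.58, 20 of 20) and 60 to 70 Mb of chromosome 11 (-0.48, 156 of 166). Further stretches were higher, such as the 10 Mb at the start of chromosome 7 (median 0.43, 44 of 56 genes higher) and of chromosome 12 (0.39, 55 of 63) and the stretch of chromosome 5 from 170 to 180 Mb (0.32, 53 of 63). Genes named above that lie beyond 50 Mb of chromosome 4 are CCNA2, NFKB1, ELOVL6, RPS3A and CPE. Of the changed genes 20.6% had neighbours whose median lay beyond 0.2. After the median of neighbouring genes was taken out, 8603 of 19604 genes passed, 5049 higher and 3554 lower, 7420 of them shared with the fit without it.

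**Figure D3:**
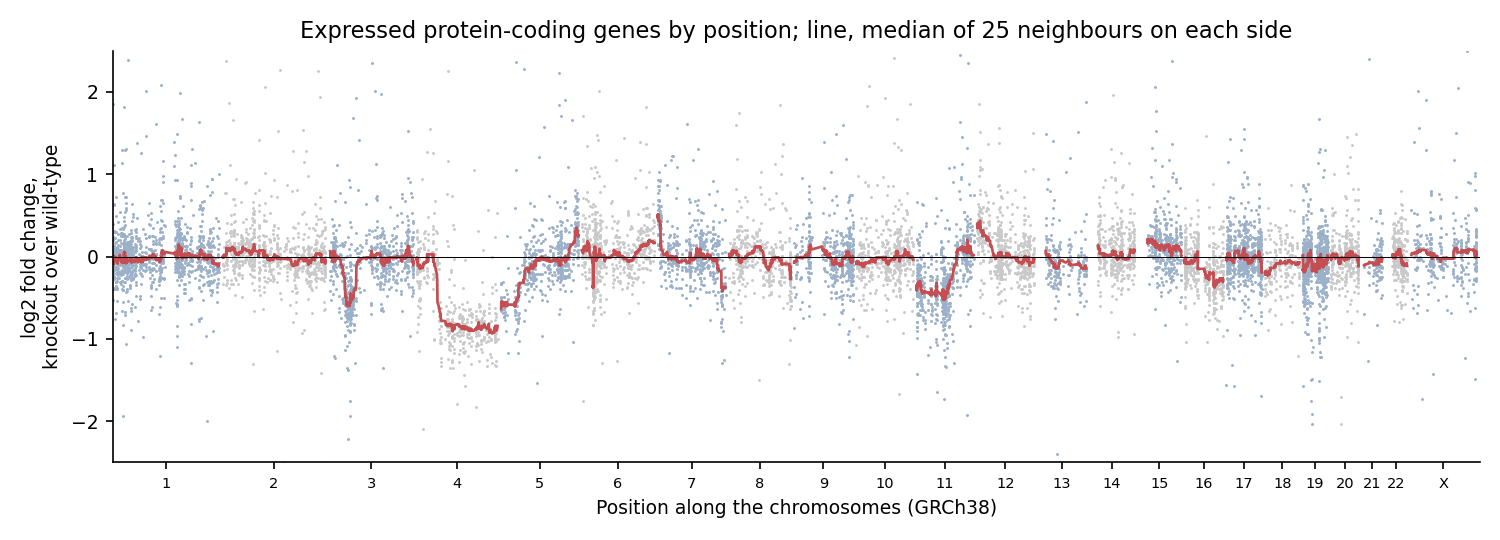
Log2 change of expressed protein-coding genes along the chromosomes, knockout against wild-type, with a line for the median of 25 neighbours on each side. The vertical axis runs from -2.5 to 2.5 and genes beyond it are not drawn, and the line drops on chromosome 4 past 50 Mb, where the median was -0.84.

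Zinc finger genes between 19 and 24.5 Mb of chromosome 19 fell together, a region chosen after the values were seen. The stretch is called 19p12 here, with limits set by these positions and not by the band. Of 26 tested there, 23 fell, 0 rose and 17 fell at least 4-fold, against 7 of 414 zinc finger genes elsewhere (Fisher's exact test, two-sided, p = 5.25e-19, for a region chosen from these data). ZNF91 fell from 19.5 ± 1.74 to 0.724 ± 0.222 CPM and ZNF100 from 19.4 ± 1.44 to 0.149 ± 0.0841 CPM (n = 4 each), whereas ZNF726, which lies between fallen genes, stood at 6.03 ± 0.801 and 5.83 ± 0.610 CPM. The fall was not limited to zinc finger genes, as other transcripts there, named after their values were seen, show. LINC01224 and ENSG00000267383 fell with log2 changes of -5.70 and -4.12, while PCGF7P (0.13) and ENSG00000213985 (-0.00019) did not pass.

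**Figure D4:**
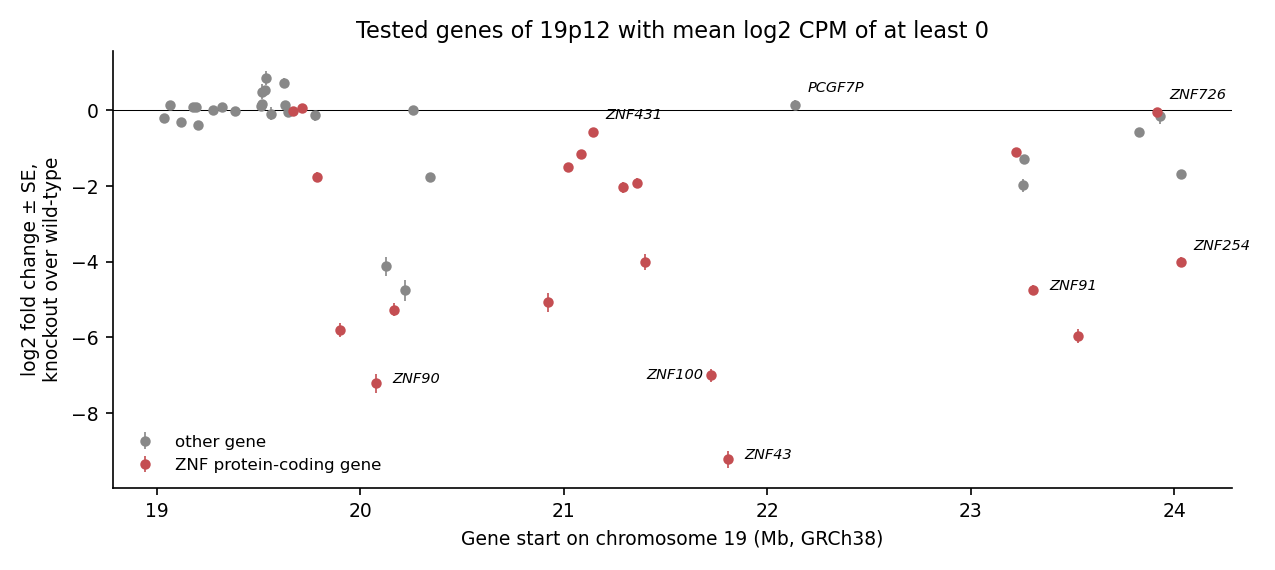
Log2 change ± SE of the tested genes of chromosome 19 between 19 and 24.5 Mb with a mean log2 CPM of at least 0, by position. Zinc finger genes reach -9.22 for ZNF43, while ZNF726 lies at -0.05.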

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

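The 219 groups examined here for a distant sample comprise the named genes and the measures of each library, by a fixed rule, and no test in this part was chosen after the result was seen. A sample was picked out where its gap to the nearest other sample of its group, divided by the range of the group, was above Dixon's 95% critical value for 4 samples. Chance flags about 1 in 20 groups, or 10.95 of the 219, and 17 were found. Of these, 7 concerned knockout replicate 5, 5 wild-type replicate 3, 3 knockout replicate 1, 1 wild-type replicate 5 and 1 knockout replicate 2.

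In knockout replicate 5 the share of counts taken by the top gene was 1.48% against 1.70% to 1.75% in the other knockout samples (gap ratio 0.843). Its MYCL level was 0.773 CPM against 1.07 to 1.10 (0.890), its DHCR7 level 35.8 CPM against 41.9 to 43.1 (0.844), its SREBF2 level 81.7 CPM against 99.1 to 99.993 (0.952) and its CD8A level 1.98 CPM against 2.57 to 2.63 (0.906). CCDC8 and ZNF43 had 0 counts there and 0.0204 to 0.0211 CPM, the level of 1 count, in the other knockout samples (0.967 for each gene).

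In wild-type replicate 3 ZNF43 stood at 9.81 CPM against 11.05 to 11.3 in the other wild-type samples (gap ratio 0.845) and IRAK3 at 7.04 CPM against 8.72 to 8.99 (0.860). There AFAP1-AS1 stood at 138 CPM against 117 to 119 (0.905), ERAP1 at 89.4 CPM against 80.6 to 81.5 (0.895) and CSF1 at 62.0 CPM against 78.1 to 78.6 (0.967). In knockout replicate 1 MXI1 stood at 12.5 CPM against 13.7 to 13.9 (0.876), PCDH17 at 3.86 CPM against 5.54 to 5.87 (0.834) and NDUFV1 at 74.5 CPM against 67.7 to 68.2 (0.936). FPR2 stood at 0.283 CPM in wild-type replicate 5 against 0.0634 to 0.0751 in the others (0.947). All 3 counts of ASRGL1 in the knockout group fell in replicate 2 (0.0632 CPM, gap ratio 1).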

How the results depend on the processing

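Regional centring and the fit without genes in shifted neighbourhoods were chosen after the data were seen, and the other alternatives before the data were examined. DOT1L was lower and past the threshold in every setting run, from -0.41 to -0.33 when each sample was left out and -0.20 after regional centring. Of the 103 other named genes, 95 kept their side of the threshold in all settings, and those past it kept their direction. MLXIP, MLXIPL and MNT, which did not pass, changed sign in at least 1 setting (MLXIP from -0.01 to 0.07 after regional centring), as did MXD3. MLX lost its call in 7 settings, MXD3 gained one in 5 and MXD4 in 1. GAPDH, KDM2A, GNL3 and NDUFV1 lost theirs after regional centring, and FOXM1 went from 0.38 to -0.0235 (adjusted p = 0.701), since the median of its neighbours, 0.40, was taken out. Of the 31 lists, 7 kept their side of the threshold in all settings and 0 of those called reversed.

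With the replicate number as a block, 10472 genes passed, 5286 higher and 5186 lower, and the same 11 lists were called. Besides MXD3 the block changed no other call of a gene named by the rule or of a list. Of the MYC network and Mondo targets 12 genes passed with the block, against 10 without it. Leaving out each sample in turn gave 8463 to 9606 changed genes, 4210 to 4959 higher and 4253 to 4647 lower, 1370 to 1536 higher and 534 to 606 lower by at least 2-fold. It gave 9 to 11 genes of the MYC network and Mondo targets, 96 to 98 named genes past the threshold and 9 to 14 lists, the fewest without wild-type replicate 5 and the most without wild-type replicate 3.

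The count of genes changed at least 2-fold moved by more than 1.5 times in 4 settings. It was 336 higher and 246 lower with limma on the authors' variance-stabilized values, which shrink the changes of low genes. It was 2257 higher and 791 lower among all 37527 genes with at least 1 count, and 412 higher and 243 lower among the 13343 genes of mean log2 CPM of at least 1, where more or fewer genes were tested. Without genes in shifted neighbourhoods 323 were lower, of 16771 genes tested. The 11 called lists became 0 with camera's estimated correlation, where 1 list had an unadjusted p below 0.05, and 23 with fry, which asks another question. The first component held 96.7% of the variance of the variance-stabilized values, and the cause was not tested. Depth limits the genes with 0 to 3 counts in a group, for which ratios carry wide counting intervals.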

Other observations

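Gene families defined by the letters of their symbols, the protocadherin clusters, genes that went on or off, the order of genes along chromosomes, the dose of the chromosome 4 segment, the loss of a segment at 19p12 and the effect of depth on detection were tested only after the results were seen. The tests of GC content and length, of reads shared between paralogs, of evenly spread genomic DNA and of other splits were written before their results were seen.

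Keratin genes, which encode the intermediate filaments of epithelial cells, rose almost together. Of 14 genes with the stem KRT, including the antisense-named KRT10-AS1, 13 rose and 1, KRT19, fell (camera adjusted p = 0.000186 over 165 families, adjusted p = 0.340 with an estimated correlation), with the same counts under each scaling. KRT81 rose from 168 ± 13.1 to 497 ± 45.1 CPM, KRT7 from 199 ± 32.3 to 364 ± 57.5 CPM and KRT18 from 288 ± 10.4 to 362 ± 16.9 CPM, while KRT19 fell from 79.4 ± 8.71 to 50.3 ± 7.40 CPM (SD, n = 4 each). Sharing of reads between keratin genes was not tested. Of 13 genes with the stem MMP, the matrix metalloproteinases and MMP24OS, 7 rose, 1, MMP19, fell and 5 did not pass (camera adjusted p = 0.0423, adjusted p = 0.941 with an estimated correlation). MMP1, the interstitial collagenase, rose from 666 ± 252 to 2063 ± 281 CPM. Of 49 genes with the stem RPL, which overlap the ribosomal protein list, 4 rose and 35 fell (camera adjusted p = 0.0141, adjusted p = 0.941 with an estimated correlation). These were the 3 families called of the 165.

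Clustered protocadherins, adhesion proteins of neurons, changed in all 3 clusters, with members of both directions in the beta and gamma clusters. All 3 tested PCDHA genes rose, PCDHA13 from 0.0640 ± 0.0440 to 1.34 ± 0.322 CPM, PCDHAC1 from 0.0922 ± 0.0230 to 2.69 ± 0.163 CPM and PCDHAC2 from 0.0939 ± 0.0574 to 1.90 ± 0.135 CPM (SD, n = 4 each). Of 13 PCDHB genes 5 rose and 5 fell, and of 15 PCDHG genes 2 rose and 7 fell, the latter becoming 3 and 5 with library totals or upper-quartile scaling. The difference between clusters was not tested, nor was the sharing of reads between genes of a cluster, so these genes may not count separately. With a mean under 0.1 CPM in one group and at least 1 CPM in the other, 24 protein-coding genes went on in the knockout and 30 went off. Those that went on include PREX2 and RUNX1T1, and those that went off include GAL, GYPC, MAGEA12 and DMD. CDKN2A, CDKN2B and MTAP had 0 counts in all 8 samples.

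Of 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many changed genes, with 9458 against 0 for the highest of the others, also among the 8 splits that part all pairs. Over the 35 splits, which set the pairing aside, the real one was alone, a share under 0.05. The 8 that part all pairs are too few for such a share, so with the pairing kept these splits do not exclude chance. EdgeR's test gave 10618 genes at an unadjusted p below 0.05 for the real split and at most 1853 for another. The real split called 10 of 25 genes of the MYC network and Mondo targets, and the others 0. Since those splits called 0 genes of any kind, this says nothing about these genes in particular. Of all genes tested the real split called 47.6%. For lists, 8 of the 35 splits called as many as the real one, 11 against a highest other of 16, and 11 among the splits that part all pairs. Chance is therefore not excluded for the number of lists.

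Whole stretches of neighbouring genes shifted together, chiefly chromosome 4 beyond 50 Mb, with further downward shifts on chromosomes 3 (-0.58 at 40 to 50 Mb) and 5 (-0.58 in the first 10 Mb) and smaller upward ones, such as 0.43 at the start of chromosome 7. In 1000 shuffles of genes among positions at most 1 window of 10 Mb shifted by at least 0.5, against 20 of 282 seen, all 20 of that size downward (permutation p = 0.001, the smallest the shuffles can give), and genes elsewhere matched on GC content, length and expression had a median of -0.0180, which argues against chance order and sequence bias. A lower dose of the segment in the knockout cells is a candidate explanation, as 94.8% of the 267 genes lay below 0 with a median ratio of 0.557 and a spread (MAD 0.234) close to that elsewhere (0.225). No DNA copy number was analysed here, and either group may carry the difference, for instance as a clone picked from a mixed line. Whether such a difference has any link to DOT1L was not tested.

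The fall of zinc finger genes at 19p12 took 17 genes down at least 4-fold. Loss of a single continuous segment was tested by the expressed zinc finger genes lying between them, of which 6 of 17 kept more than 25% of the wild-type level, among them ZNF431 and ZNF726, which argues against it. This test replaced one on neighbouring genes of all types that had too few genes to decide, and it was chosen after its values were seen. Reads shared between paralogs are argued against by the small share of 50-base words that the fallen genes have in common with other transcripts, a median of 4.51% (0.833% to 10.1%). Silencing of the cluster in the knockout cells may account for it and was not tested, nor was a difference between clones.

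More genes had at least 10 counts in the knockout libraries, 20049 to 20393 against 18987 to 19442 in wild-type. Deeper sequencing does not account for it, since after thinning each library to the lowest total the lowest knockout library still lay 526 genes above the highest wild-type one. Genomic DNA spread evenly over genes was tested on genes silent in wild-type. A mean of 23.75 of them reached 10 counts per knockout library, where an even spread gives 0.000746. Genes switched on would give such an excess with or without DNA, and they are few beside the gap, so this count does not decide. In each knockout library 93.1% to 93.8% of the 26463 genes silent in wild-type had 0 counts. Any evenly spread DNA was therefore thin and left most of these genes without a count. How many genes such thin counts would lift to 10 was not tested, so DNA as a source of the gap stays open. Counts on 381 olfactory receptor genes were 617 to 1014 in knockout and 314 to 457 in wild-type libraries. They lay on 45 to 60 of these genes in knockout and 22 to 30 in wild-type libraries. A thin even spread would also leave most of these genes without a count, so the olfactory counts do not decide either. A wider range of transcribed genes in the knockout cells may account for the higher number of genes, and it was not tested apart from differences between clones.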
